A study of Homo sapiens with 16 samples.

How the data were processed

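Gene expression was measured on Agilent 2-colour arrays in CD14-positive monocytes of 5 healthy donors. The cells had been enriched from blood by depletion of other cells and then selected on CD14 beads. Culture lasted 6 hours in GM-CSF at 50 ng/ml, without a further cytokine or with IL-4, KFR or Super-4 at 20 ng/ml. On every array the Cy3 channel held GM-CSF alone and the Cy5 channel held GM-CSF with a cytokine, so each array gives a ratio within 1 donor. No array has the dyes exchanged. There were 16 arrays on 2 slides: 5 donors for each of the 3 cytokines, and a repeat array of donor 1 with IL-4.

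The deposited scanner files give, per the file headers, spot intensity in each channel as extracted by Agilent Feature Extraction 10.7.3.1 from array design 028004, with local background and with probe positions on hg19. The authors also deposited a value table of log10 ratios, Cy5 over Cy3, after the dye normalization of Feature Extraction. Checked against the scanner files, this table held their log ratio column, with a largest difference of 0. The deposited flags per spot, which are of another kind (other), mark spots well above background, saturated spots and spots that are uneven or stray from their copies.

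The ratios used here were recomputed from the mean spot intensity. R 4.3.3 was used with limma 3.58.1, with version 1.17.8 of data.table and with jsonlite 2.0.0. Background was corrected by the normexp method with an offset of 50, and each array was normalised by loess, with control spots given no weight. Of 62976 spots per array, 58717 were gene spots carrying 42405 different probes. Spots marked as uneven or straying in either channel were left out (561 to 1099 per array), and copies of a probe were averaged. The 2 arrays of donor 1 with IL-4 were averaged, which left 15 ratios, 5 per cytokine.

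Probes were named from the reference gene table by transcript accession (25422 probes), by another accession of the probe (180), by symbol (1039) or by synonym (345). The other 15419 probes kept the name given in the files. In all, 34591 different gene names were found, 20307 of them in the reference table. The 136 probes of Y-linked genes and XIST were left out. A probe was kept when it lay well above background in either channel for at least 5 of the 15 ratios and had at most 2 missing ratios. Each gene was represented by its brightest kept probe. This left 21699 genes, 14165 of them with an official symbol.

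Between 43.1% and 93.2% of gene spots lay well above background in Cy3 and between 40.4% and 82.7% in Cy5. Median spot signal, with background not subtracted, was 51.7 to 206 in Cy3 and 41.6 to 119 in Cy5. Median local background was 25 to 29 and 37 to 39.5, and no spot was saturated. The log ratios of the spike-in controls followed their designed ratios with a slope of 0.855 to 0.906 and a correlation of 0.980 to 0.991 across spike-ins.

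A linear model with 1 mean per cytokine was fitted to the log2 ratios in limma, with 12 residual degrees of freedom and moderated variances (prior degrees of freedom 3.69). Each mean was tested against 0, which is the comparison with GM-CSF alone, and the means were compared with each other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a further count required at least a 2-fold change. Donor was not a term in the model, and fits with donor as a fixed or random block were alternatives. In a ratio tested against 0, the spread of the GM-CSF control is part of the ratio and has no term of its own. A dye effect of a single gene would add to its ratio against GM-CSF and cancels between cytokines. The 3 arrays of a donor share the same GM-CSF condition, so chance values may be shared between the comparisons against GM-CSF. The labels do not say whether the GM-CSF RNA on them was the same, nor whether the repeat array was a new labelling or a new culture.

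The procedure was tested on simulated data for 21699 genes, in which each known change was given to 66 to 134 genes per comparison and 21262 to 21499 genes were unchanged. Against GM-CSF, 2-fold changes were recovered for 73.1% of genes with IL-4, 85.8% with Super-4 and 82.1% with KFR. Of the calls, 7.64%, 5.44% and 6.78% were false. Between cytokines, 70.1% of 2-fold and 29.9% of 1.5-fold changes between Super-4 and IL-4 were recovered, with 0.826% false calls. A simulated 4-fold change was read as 2.46-fold with IL-4. With donor as a fixed block, false calls were 27.7%, 28.7% and 40.5% of calls against GM-CSF. Between Super-4 and IL-4 they were 4.76%, and the recovery of 1.5-fold changes rose from 29.9% to 49.3%. Between KFR and Super-4 false calls rose from 0 to 8.05%, and that recovery from 37.3% to 46.3%.

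The 26 gene lists cover IL-4 response genes of monocytes and macrophages, dendritic cell differentiation markers, monocyte and macrophage markers, antigen presentation and costimulation, inflammatory cytokines and chemokines, interferon-stimulated genes, IL-4 receptor chains and JAK-STAT components, JAK-STAT feedback and immediate targets, eicosanoid and PPAR-gamma lipid genes, C-type lectins and scavenger receptors, pattern recognition receptors and adaptors, chemokine receptors, and myeloid transcription factors. They also cover glycolysis and hypoxia, cholesterol synthesis, cell cycle, immediate early and heat shock, and housekeeping genes. Lists of T cell, B cell, natural killer cell, platelet, erythroid, neutrophil, basophil and mast cell, and plasmacytoid dendritic cell markers stand for other blood cells. Each list was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it.

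The score of the IL-4 response list is the mean log2 ratio over its members on each array. The cytokines were compared by a 2-sided exact permutation test over the 252 splits of 5 against 5 ratios, whose smallest p is 0.00794, and by an exact sign-flip test over the 32 sign patterns of 5 donors, whose smallest p is 0.0625. Response size is the mean log2 ratio, signed by direction, over genes that changed at least 2-fold in the mean of the 3 cytokines, a gene set chosen after the data were seen. Under each alternative these genes were chosen again, and response size was also taken over the genes of the reported fit.

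The tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, apart from those said here or in the closing section to have been added later. The rule named, against GM-CSF, the 12 largest rises and 8 largest falls among called genes with an official symbol that moved the same way in 5 of 5 donors. Between cytokines it named up to 8 called genes each way or, where fewer than 3 passed, the 5 genes with the smallest p. The rule also left out genes well above background in neither group, a step that was not applied between cytokines. It also named 21 genes in advance, and 2 to 4 members with the smallest p of each list described. IL13RA2, one of the 21, did not pass the filter. Members that went against their list (MYC, CHI3L1, OCSTAMP, CCL5, PTGS2, ALOX5AP, LTA4H, ALOX5, ABCG1, STAB1, CSF1R, FCN1) and CXCR2, CD36, SCARB1 and PPBP were chosen after their values were seen.

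The alternatives were no background correction, median centring in place of loess, scale normalization between arrays, the processed signals of Feature Extraction, the deposited value table, no filter, a filter on all 15 ratios, the mean of all probes of a gene, array weights, a variance trend, only the groups compared, the slide or the donor as a block, the other thresholds of 0.01 and 0.1, no repeat array, and leaving out each donor in turn. Those added after the data were seen were each slide alone, leaving out arrays that stood apart, and the repeat array in place of the mean. Where these left different donors in 2 groups, scores were also compared over the donors with both cytokines. Exon and UTR annotation was not analysed here.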

Results

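GM-CSF together with IL-4 turns blood monocytes into dendritic cells, and these arrays show the first hours of that response. CD14-positive monocytes of 5 healthy donors were kept for 6 hours in GM-CSF at 50 ng/ml, and in GM-CSF with IL-4, Super-4 or KFR at 20 ng/ml. Super-4 and KFR are engineered forms of IL-4, known as superkines. Super-4 binds the common gamma chain of the type I receptor more tightly, and KFR binds the IL-13 receptor chain alpha-1 of the type II receptor more tightly. Each array set a combination (Cy5) against GM-CSF alone (Cy3) of the same donor. There were 16 arrays, with 5 donors for each cytokine and a repeat array for donor 1 with IL-4, and they gave 15 ratios for 21699 genes. Spots well above background made up 43.1% to 93.2% of gene spots in the GM-CSF channel and 40.4% to 82.7% in the combination channel. Below, values are mean log2 ratios over GM-CSF alone ± SD, n = 5 donors, and a gene rose or fell where the adjusted p of the limma test was under 0.05.

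IL-4 was compared with GM-CSF alone to find what it adds within 6 hours. The largest rise was that of MAOA, monoamine oxidase A, at 5.25 ± 0.21, or 37.9-fold. The chemokines CCL17 and CCL26 rose by 4.28 ± 0.31 (19.4-fold) and 3.95 ± 0.14 (15.5-fold). The largest fall was that of the monocyte-attracting chemokine CCL2, at -4.10 ± 0.71, a 17.1-fold decrease. The neutrophil-attracting chemokines CXCL3, CXCL1 and CXCL6 fell to -3.73 ± 0.59, -3.50 ± 0.75 and -3.37 ± 0.91. A second probe for CXCL1, nearly as bright, showed a smaller fall (-2.03 with IL-4, -1.64 with Super-4 and -1.92 with KFR). CD14, the monocyte surface marker on which the cells were selected, fell to -1.98 ± 0.20, while the dendritic cell lectin CD209 rose by 2.14 ± 0.30. In all, 2637 genes rose and 3950 fell, and 726 of these changed at least 2-fold, 307 up and 419 down. A further count of genes with an unadjusted p under 0.05 was 8645.

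The other genes with the largest rises were SLA, an adaptor that dampens receptor signalling (4.33 ± 0.59), NFXL1 (4.00 ± 0.74), the lysosomal acid lipase LIPA (3.74 ± 0.62), the protease inhibitor SPINT2 (3.22 ± 0.35), the pseudogene CXCR2P1 (3.21 ± 0.77), the IgE receptor chain FCER1A (3.15 ± 0.63), the noncoding RNA MIR503HG (3.14 ± 0.45), the lectin CLEC10A (3.11 ± 0.74) and MS4A4A (8.56-fold, with an SD of 0.34 on the log2 scale). The other largest falls were those of the hepatocyte growth factor receptor MET (-3.79 ± 0.70), PID1 (-3.76 ± 0.40), OLIG1 (-3.63 ± 0.43) and the chemokine CCL7 (-3.38 ± 0.76). All 20 genes moved the same way in 5 of 5 donors, with adjusted p from 2.56e-14 for CCL26 to 1.31e-04 for CXCL6. On hg19, the probe for MAOA lies on chromosome X at 43606008 to 43606067, that for CCL17 on chromosome 16 at 57449888 to 57449947 and that for CCL2 on chromosome 17 at 32584050 to 32584109.

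Known IL-4 response genes rose together. Of 37 measured, 32 rose, 2 fell and 3 did not pass (32 and 2 when adjusted over the list alone). Their median was 1.72, with a camera adjusted p of 4.27e-28 (adjusted p = 0.00264 with an estimated correlation). Besides MAOA, CCL17 and CCL26, the low-affinity IgE receptor FCER2 rose by 2.71 ± 0.40, the lipoxygenase ALOX15 by 2.13 ± 0.37, the lipid-sensing nuclear receptor PPARG by 1.82 ± 0.28, the signalling inhibitor CISH by 1.00 ± 0.07 and its relative SOCS1 by 0.57 ± 0.10. The 2 members that fell were the growth regulator MYC (-1.28 ± 0.71) and CHI3L1 (-0.22 ± 0.20). Smaller rises were those of the mannose receptor MRC1 (0.49 ± 0.34, adjusted p = 0.00782), the programmed death ligand PDCD1LG2 (0.47 ± 0.37, adjusted p = 0.00694) and CCL22 (0.31 ± 0.15, adjusted p = 0.00882), which lay well above background on at most 3 of 5 arrays. PDCD1LG2 and CCL22 were dim (mean log2 intensity 6.31 and 6.16, against 12.3 for MRC1), so the size of their rise is uncertain. Leaving out a single donor ended 4 of these small calls. CHI3L1 was at -0.23 without donor 1, -0.19 without donor 4 and -0.16 without donor 5, PDCD1LG2 at 0.35 without donor 5, CCL22 at 0.28 without donor 3 and MRC1 at 0.46 without donor 4. Under median centring in place of loess, MRC1, CISH and SOCS1 read as lower (-0.94, -0.46 and -0.87).

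Dendritic cell markers rose as well, with 19 of 24 up, 1 down and 4 not passing, the same counts adjusted over the list alone. Their median was 0.95, with a camera adjusted p of 1.30e-11 (adjusted p = 0.0153 with an estimated correlation). The transcription factor IRF4 rose by 1.59 ± 0.60 and the lipid-antigen receptor CD1C by 1.20 ± 0.48, although CD1C lay well above background in GM-CSF alone on 1 array only. CD1A stood at 0.57 ± 0.40 and did not pass (adjusted p = 0.134). The member that fell was the cell fusion gene OCSTAMP, at -0.68 ± 0.32, and its call ended without donor 5 (-0.58). Among 23 antigen presentation and costimulation genes 8 rose, none fell and 15 did not pass (12 up and 1 down adjusted over the list alone). Their median was 0.45, with a camera adjusted p of 1.23e-04 (adjusted p = 0.225 with an estimated correlation), and it was -0.90 under median centring, where HLA-DPA1 also read as lower (-0.91). CIITA, the master regulator of class II genes, rose by 1.84 ± 0.36, the costimulator CD86 by 1.65 ± 0.56 and HLA-DPA1 by 0.55 ± 0.25.

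Lipid mediator genes moved in both directions. Of 30 eicosanoid and PPAR-gamma lipid genes 20 rose, 6 fell and 4 did not pass (20 and 7 adjusted over the list alone), with a median of 0.69. They had a camera adjusted p of 9.19e-06 (adjusted p = 0.0449 with an estimated correlation). PDK4, which spares glucose for fat burning, rose by 2.77 ± 0.47. The falls included the prostaglandin synthase PTGS2 (-3.22 ± 0.60), the cholesterol exporters ABCA1 (-1.44 ± 0.25) and ABCG1 (-0.43 ± 0.14), and the leukotriene pathway genes LTA4H (-1.04 ± 0.17), ALOX5AP (-0.96 ± 0.33) and ALOX5 (-0.23 ± 0.20). The call for ALOX5 ended without donor 1 (-0.18), donor 2 (-0.20) or donor 5 (-0.20).

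Of 27 inflammatory cytokines and chemokines 25 fell, 1 rose and 1 did not pass, the same adjusted over the list alone. Their median was -1.38, with a camera adjusted p of 4.33e-15 (adjusted p = 0.00449 with an estimated correlation). CCL5, a T cell attractant, was the member that rose, by 1.49 ± 0.34. Monocyte and macrophage markers fell for 11 of 24, rose for 3 and did not pass for 10 (14 down and 3 up adjusted over the list alone). Their median was -0.25, with a camera adjusted p of 0.00497 (adjusted p = 0.221 with an estimated correlation). The scavenger receptors MARCO and CD163 fell to -1.63 ± 0.14 and -1.01 ± 0.35, and the formyl peptide receptor FPR1 to -1.16 ± 0.17. The 3 that rose, STAB1 (1.35 ± 0.73), FCN1 (0.63 ± 0.24) and the growth factor receptor CSF1R (0.33 ± 0.09), read as lower with median centring (-0.09, -0.83 and -1.13). Pattern recognition receptors and adaptors fell for 13 of 23, rose for 5 and did not pass for 5 (15 down and 5 up adjusted over the list alone). Their median was -0.42, with a camera adjusted p of 0.00497 (adjusted p = 0.189 with an estimated correlation). IRAK3 and NLRP12, both brakes on this signalling, were at -1.25 ± 0.17 and -1.05 ± 0.23.

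Interferon-stimulated genes fell for 15 of 36, rose for 2 and did not pass for 19 (16 down and 3 up adjusted over the list alone). Their median was -0.29, with a camera adjusted p of 0.00497 (adjusted p = 0.436 with an estimated correlation) that did not pass without donor 3 (adjusted p = 0.0503). IFI44, ISG20 and the signal transducer STAT2 were at -0.96 ± 0.26, -0.93 ± 0.23 and -0.80 ± 0.24. Cholesterol synthesis genes fell for 7 of 20, rose for 1 and did not pass for 12, the same adjusted over the list alone. The falls included INSIG1 (-1.12 ± 0.39), LSS (-0.96 ± 0.20) and HSD17B7 (-0.37 ± 0.16). The median was -0.20, with a camera adjusted p of 0.0216 (adjusted p = 0.394 with an estimated correlation, and 0.124 without donor 3). Of 32 myeloid transcription factors 13 rose, 7 fell and 12 did not pass (14 and 8 adjusted over the list alone). Their median was 0.12, and -1.20 under median centring, with a camera adjusted p of 0.0439 (adjusted p = 0.225 with an estimated correlation, 0.107 without donor 2 and 0.053 without donor 4). MAF rose by 2.99 ± 0.61 and BHLHE41 fell to -2.11 ± 0.33. Immediate early and heat shock genes rose for 8 of 23, fell for 3 and did not pass for 12 (8 and 4 adjusted over the list alone). Their median was 0.33, with a camera adjusted p of 0.00497 (adjusted p = 0.189 with an estimated correlation). HSPB1 was at 1.29 ± 0.24, FOS at 1.09 ± 0.39 and HSPA1A at 0.83 ± 0.08, and the list and these 3 genes read as lower under median centring (median -1.13).

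The receptor chains themselves were slightly lower: IL4R was at -0.47 ± 0.24 and IL13RA1 at -0.41 ± 0.22, and IL2RG, the common gamma chain, was at -0.34 ± 0.26 (adjusted p = 0.0334). A second, dimmer probe for IL2RG gave 0.48, and the call ended without donor 1 (-0.29), donor 2 (-0.34) or donor 3 (-0.26). As a list, IL-4 receptor chains and JAK-STAT components rose for 5 of 24, fell for 8 and did not pass for 11, the same adjusted over the list alone. Their camera adjusted p was 0.849, with a median of 0.06 and a mean just below 0. Glycolysis and hypoxia genes rose for 4 of 25 and fell for 6 (6 and 6 adjusted over the list alone), with a median of 0.08, a mean of -0.02 and a camera adjusted p of 0.577. Cell cycle genes rose for 5 of 18 and fell for 3 (5 and 4 adjusted over the list alone), with a median of 0.01, a mean of -0.04 and a camera adjusted p of 0.523. Housekeeping genes rose for 6 of 18 and fell for 1, the same adjusted over the list alone, with a median of 0.12 and a camera adjusted p of 0.103.

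Camera called no list of markers of other blood cells. Fry, which tests a list against no change, called those of plasmacytoid dendritic cells (adjusted p = 5.55e-05), neutrophils (3.25e-04), natural killer cells (0.00198) and platelets (0.00862). Medians and camera adjusted p were -0.04 and 0.946 for 13 T cell markers, -0.03 and 0.918 for 9 B cell markers, -0.05 and 0.339 for 8 natural killer cell markers, -0.04 and 0.313 for 11 platelet markers, and -0.01 and 0.966 for 7 erythroid markers. They were 0.06 and 0.102 for 7 neutrophil markers, -0.17 and 0.918 for 4 basophil and mast cell markers, and 0.20 and 0.0759 for 7 plasmacytoid dendritic cell markers. Adjusted over the list alone, the members that rose and fell numbered 1 and 0 for T cells, 1 and 1 for B cells, 0 and 3 for natural killer cells, 0 and 3 for platelets, 0 and 1 for erythroid cells, 2 and 0 for neutrophils, 1 and 3 for basophils and mast cells, and 3 and 0 for plasmacytoid dendritic cells. For T cell markers the mean was 0.01, for basophil and mast cell markers, which include FCER1A, it was 0.64, and camera ranked the B cell markers upward. Each of these differs in sign from the list's median.

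**Figure D1:**
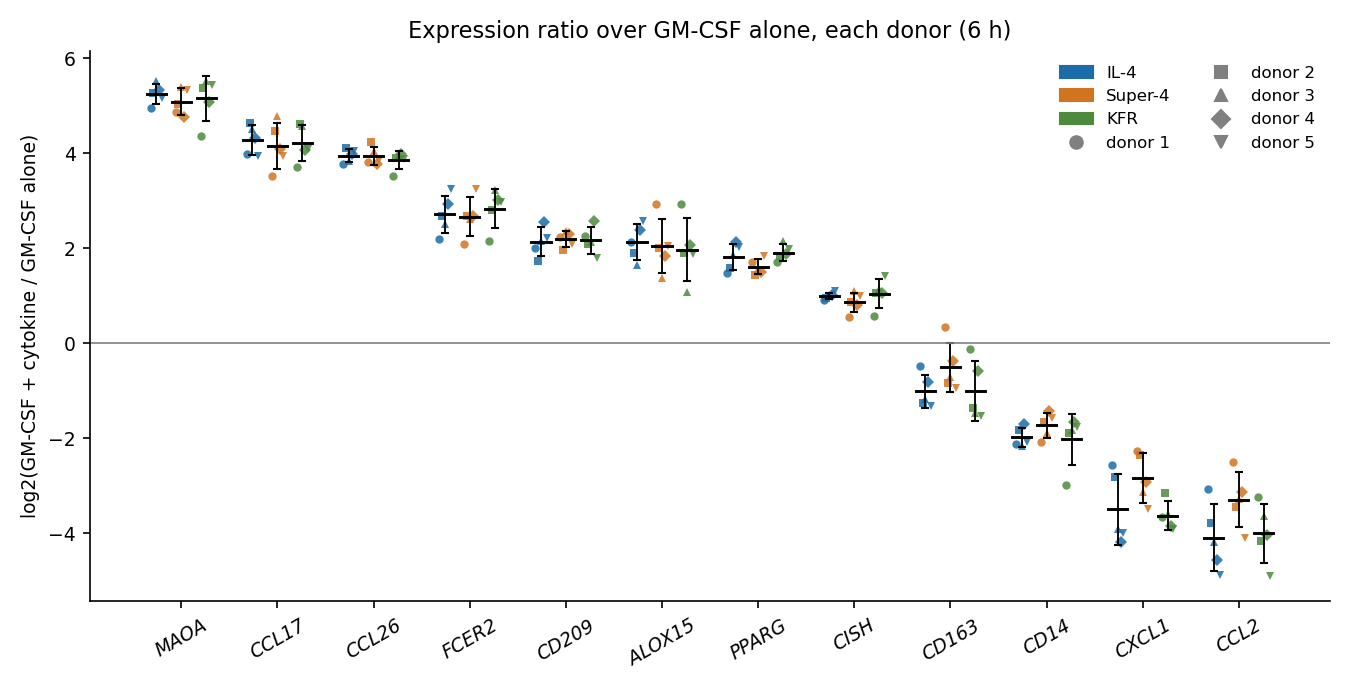
Log2 expression ratio of 12 genes over GM-CSF alone after 6 hours (vertical axis), for IL-4, Super-4 and KFR, with 1 symbol per donor and the mean ± SD of 5 donors in black. MAOA, CCL17 and CCL26 lie highest and CCL2 lowest for each cytokine, and CISH, which rose here, read as lower when arrays were centred on their median.

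**Figure D2:**
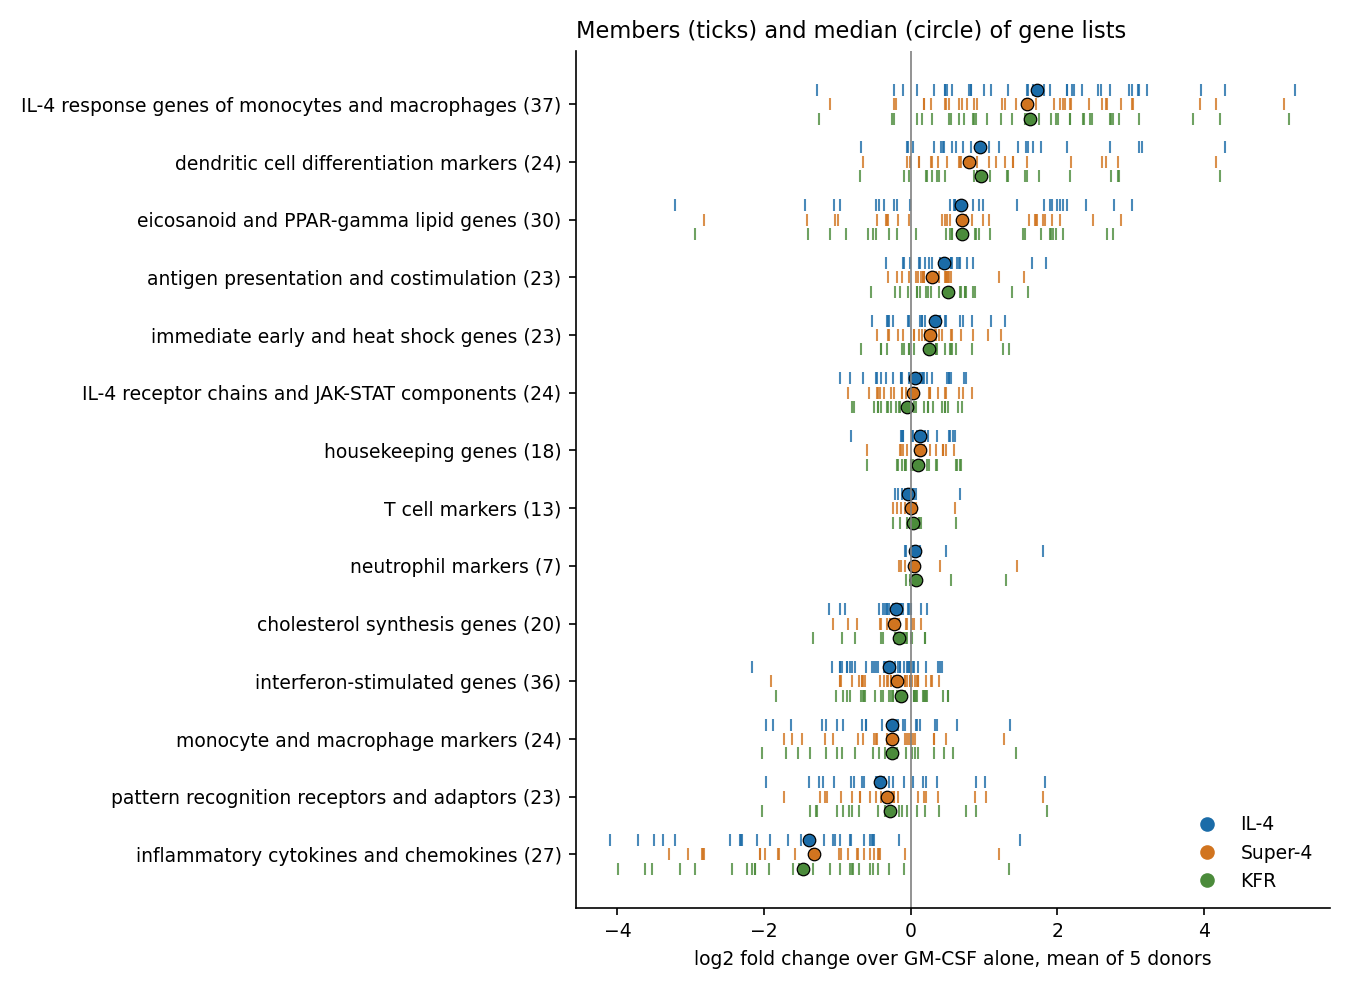
Log2 fold change over GM-CSF alone, as the mean of 5 donors (horizontal axis), of each measured member of 14 gene lists (ticks) and the list median (circle), with the number of members in parentheses. IL-4 response genes have the highest medians (1.58 to 1.72) and inflammatory cytokines and chemokines the lowest (-1.47 to -1.32), while the antigen presentation, immediate early and, with Super-4, housekeeping medians fell below 0 under median centring.

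Super-4 was compared with GM-CSF alone to find what the gamma-chain superkine adds. MAOA, CCL17 and CCL26 rose most, by 5.08 ± 0.28 (33.9-fold), 4.16 ± 0.49 (17.8-fold) and 3.95 ± 0.20 (15.4-fold), and CCL2 fell to -3.29 ± 0.58, a 9.78-fold decrease. CD209 rose by 2.19 ± 0.17, FCER2 by 2.67 ± 0.41, ALOX15 by 2.04 ± 0.57 and PPARG by 1.61 ± 0.16, and CD14 fell to -1.72 ± 0.27. In all 2306 genes rose and 3618 fell, of which 248 and 317 changed at least 2-fold, and 8139 had an unadjusted p under 0.05. The other largest rises were those of SLA (3.90 ± 0.87), NFXL1 (3.65 ± 0.60), LIPA (3.48 ± 1.34), SPINT2 (3.03 ± 0.66), MS4A4A (3.02 ± 0.26), CXCR2P1 (2.92 ± 1.05), the crosslinking enzyme TGM2 (2.87 ± 0.82), MIR503HG (2.83 ± 0.30) and FCER1A (2.83 ± 1.10). For TGM2 a second probe, nearly as bright, showed a smaller rise (1.06). The other largest falls were those of MET (-3.56 ± 0.87), OLIG1 (-3.33 ± 0.58), PID1 (-3.30 ± 0.41), the G protein regulator RGS16 (-3.05 ± 0.96), CXCL3 (-3.04 ± 0.76), CCL7 (-2.84 ± 1.22) and CXCL1 (-2.83 ± 0.52).

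With Super-4, 31 of 37 IL-4 response genes rose and 2 fell (32 and 2 adjusted over the list alone). Their median was 1.58, with a camera adjusted p of 1.37e-28 (adjusted p = 0.00244 with an estimated correlation). Dendritic cell markers rose for 15 of 24 and fell for 1 (18 and 1 adjusted over the list alone), with a median of 0.79 and a camera adjusted p of 5.34e-11 (adjusted p = 0.0187 with an estimated correlation). IRF4, CD86 and CD1C rose by 1.29 ± 0.65, 1.21 ± 0.62 and 1.07 ± 0.58, although CD1C lay well above background in GM-CSF alone on 2 of 5 arrays only. Inflammatory cytokines and chemokines fell for 23 of 27 and rose for 1 (25 and 1 adjusted over the list alone). Their median was -1.32, with a camera adjusted p of 1.45e-13 (adjusted p = 0.00704 with an estimated correlation). For eicosanoid and PPAR-gamma lipid genes, 18 of 30 rose and 6 fell (20 and 6 adjusted over the list alone), with a median of 0.70. The camera adjusted p was 1.81e-05 (adjusted p = 0.0533 with an estimated correlation), and PDK4 rose by 2.48 ± 0.38. Camera also called the monocyte markers (10 of 24 down and 3 up), pattern recognition genes (12 of 23 down and 5 up), interferon-stimulated genes (10 of 36 down and 1 up) and cholesterol synthesis genes (8 of 20 down). It further called antigen presentation genes (4 of 23 up and 1 down), immediate early genes (9 of 23 up and 2 down) and housekeeping genes (7 of 18 up and 2 down). Adjusted over the list alone these were 12 and 3, 15 and 5, 12 and 2, 8 and 0, 4 and 1, 9 and 2, and 7 and 2. These 7 calls were lost, in that order, at adjusted p = 0.265, 0.155, 0.577, 0.348, 0.374, 0.121 and 0.155 with an estimated correlation, and the last 3 lists read as lower under median centring. The interferon list was also lost without donor 2, 3 or 5 (adjusted p = 0.0882, 0.298 and 0.0553), the cholesterol list without donor 3 (0.0632) and the housekeeping list without donor 1, 3 or 5 (0.0663, 0.0574 and 0.0627). ACTB (0.59 ± 0.30) and PPIA (0.44 ± 0.21) were above 0 and TUBB (-0.59 ± 0.37) below 0, and CD274, the ligand of PD-1, was at 0.54 ± 0.29. For ACTB a second, dimmer probe gave 0.02 only. Under median centring ACTB, PPIA and CD274 changed direction and TUBB did not. CD163 was at -0.51 ± 0.52 and did not pass (adjusted p = 0.0786), but passed at -0.72 without donor 1. PDCD1LG2 at 0.17 ± 0.23, CD1A at 0.66 ± 0.77 and IL2RG at -0.27 ± 0.25 did not pass either (adjusted p = 0.314, 0.0877 and 0.0886). Camera called no list of markers of other blood cells, whereas fry called the natural killer, erythroid and neutrophil lists (adjusted p = 0.0133 each), the platelet list (0.0285) and the plasmacytoid dendritic cell list (2.31e-04).

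KFR was compared with GM-CSF alone to find what the superkine directed to the type II receptor adds. MAOA rose by 5.16 ± 0.47 (35.7-fold), CCL17 by 4.21 ± 0.38 (18.5-fold) and CCL26 by 3.85 ± 0.19 (14.5-fold), and CCL2 fell 16.0-fold, with an SD of 0.62 on the log2 scale. FCER2 rose by 2.84 ± 0.41, CD209 by 2.17 ± 0.28, ALOX15 by 1.97 ± 0.66 and PPARG by 1.91 ± 0.17, and CD14 and CD163 fell to -2.02 ± 0.54 and -1.01 ± 0.63. In all 2866 genes rose and 4390 fell, of which 281 and 410 changed at least 2-fold, and 9392 had an unadjusted p under 0.05. The other largest rises were those of SLA (4.00 ± 0.87), NFXL1 (3.89 ± 0.45), LIPA (3.38 ± 1.11), SPINT2 (3.11 ± 0.68), MIR503HG (2.92 ± 0.53), CXCR2P1 (2.83 ± 0.89), FCER1A (2.83 ± 0.86) and MAF (2.81 ± 0.83). The other largest falls were those of MET (-3.77 ± 0.79), PID1 (-3.76 ± 0.36), CXCL1 (-3.63 ± 0.30), OLIG1 (-3.54 ± 0.49), CXCL3 (-3.52 ± 0.58), RGS16 (-3.14 ± 0.63) and CCL7 (-3.14 ± 1.14).

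With KFR 31 of 37 IL-4 response genes rose and 2 fell (32 and 3 adjusted over the list alone). Their median was 1.62, with a camera adjusted p of 1.08e-24 (adjusted p = 0.00469 with an estimated correlation). Dendritic cell markers rose for 17 of 24 and fell for 1 (19 and 1 adjusted over the list alone), with a median of 0.96 and a camera adjusted p of 1.94e-10 (adjusted p = 0.0227 with an estimated correlation). IRF4 rose by 1.58 ± 0.69, CD86 by 1.38 ± 0.73, CD1C by 1.08 ± 0.95 and CD1A by 0.97 ± 0.82, a call that ended without donor 2 (0.88). CD1C lay well above background in GM-CSF alone on 2 of 5 arrays only. Inflammatory cytokines and chemokines fell for 23 of 27 and rose for 1 (24 and 1 adjusted over the list alone). Their median was -1.47, with a camera adjusted p of 1.01e-13 (adjusted p = 0.0067 with an estimated correlation). Eicosanoid and PPAR-gamma lipid genes rose for 20 of 30 and fell for 7 (20 and 8 adjusted over the list alone), with a median of 0.70. The camera adjusted p was 7.76e-05 (adjusted p = 0.0783 with an estimated correlation), and PDK4 rose by 2.68 ± 0.14. Camera also called antigen presentation genes (12 of 23 up and 1 down), monocyte markers (11 of 24 down and 3 up), pattern recognition genes (13 of 23 down and 5 up) and immediate early genes (8 of 23 up and 4 down). Adjusted over the list alone these were 13 and 1, 13 and 3, 13 and 5, and 9 and 4. These 4 calls were lost, in that order, at adjusted p = 0.331, 0.219, 0.199 and 0.219 with an estimated correlation, and antigen presentation and immediate early genes read as lower under median centring (-0.88 and -1.10). The immediate early list was also lost without donor 4 (adjusted p = 0.0715). PDCD1LG2 stood at 0.09 ± 0.24 and did not pass (adjusted p = 0.613). Camera called no list of markers of other blood cells here either, whereas fry called the neutrophil, basophil and mast cell, and plasmacytoid dendritic cell lists (adjusted p = 8.00e-04, 0.0469 and 6.08e-05).

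The counts against GM-CSF differed between slides and rose with a block in the model. Slide and donor go together: slide 1 held donors 1 and 2, and slide 2 held donors 4 and 5 and the repeat array of donor 1. The KFR array of donor 3 lay on slide 2 and its other arrays on slide 1. Counts of the 2 slides thus come from different donors and numbers of arrays, and a slide effect cannot be told from donors. On the arrays of slide 1 alone 3288, 3023 and 1879 genes passed with IL-4, Super-4 and KFR, on slide 2 alone 5720, 5017 and 7080, and with slide as a block 8266, 8015 and 8516. With donor as a fixed block 9468, 9050 and 10171 passed. Leaving out donor 4 gave 3941 with Super-4. Centring arrays on their median in place of loess moved the median of all genes to -0.61, -0.64 and -0.54. Of the called genes, 81.1%, 80.8% and 79.8% were then lower, against 60.0%, 61.1% and 60.5% with loess. Directions with loess are relative to genes of similar intensity on the array, and those with median centring to the middle of all spots. With the processed signals and the deposited ratios no named gene changed direction against GM-CSF.

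Super-4 was compared with IL-4 to find whether raised affinity for the gamma chain changes the response at an equal dose. For the genes that moved most the difference was small: over 640 genes that changed at least 2-fold in the mean of the 3 cytokines, the median absolute difference was 0.16 on the log2 scale. The largest difference in this set was that of CCL2, which fell less with Super-4, by 0.81 (95% interval 0.05 to 1.56, higher in 5 of 5 donors, adjusted p = 1.00). CXCL3 and CXCL1 also fell less, by 0.69 (-0.08 to 1.46) and 0.66 (0.00 to 1.33), and the lectin CLEC10A rose less, by -0.50 (-1.41 to 0.41). None of these passed, and the second probe for CXCL1 differed less, with -1.64 with Super-4 and -2.03 with IL-4 over GM-CSF alone. No gene passed in limma, where 65 genes had an unadjusted p under 0.05, nor with donor as a block, where 443 did and the smallest adjusted p was 0.311. The genes with the smallest p were 2 without a symbol, MDM1 (0.27, 0.09 to 0.46), TM6SF2 (0.23, 0.06 to 0.41) and TAMALIN-AS1 (0.21, 0.05 to 0.37). For MDM1, 2 dimmer probes differed less, with -0.34 and -0.29 with Super-4 and -0.35 and -0.31 with IL-4 over GM-CSF alone. TM6SF2 and TAMALIN-AS1 were dim, with a mean log2 intensity of 6.15 and 6.50, against 14.5 for CCL2. The interval of the difference lay within 2-fold for 79.1% of the 640 genes, and for 99.5% with donor as a block, and 7.5% of the 640 genes changed more with Super-4 than with IL-4. Intervals of single genes given here leave out the pairing by donor. Their median half-width over the 640 genes was 0.54, against 0.24 with donor as a block.

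By camera, inflammatory cytokines and chemokines were higher with Super-4 than with IL-4 (median 0.22, adjusted p = 3.42e-08), as were interferon-stimulated genes (0.07, adjusted p = 0.0359). IL-4 response genes (-0.12, adjusted p = 4.52e-04), antigen presentation genes (-0.15, adjusted p = 4.52e-04) and dendritic cell markers (-0.12, adjusted p = 0.0247) were lower. All 5 calls were lost at adjusted p = 0.084, 0.577, 0.418, 0.504 and 0.504 with an estimated correlation, and fry called none (adjusted p = 0.902 for each). These tests, like those of the other pairs of cytokines below, left out the pairing by donor, although ratios of the same donor correlated (median 0.653). With donor as a fixed block, camera at the preset correlation called more lists for this pair, as the closing section gives. Among interferon-stimulated genes, the members with the smallest p were IFIT1 (0.31, -0.26 to 0.89), MX1 (0.28, -0.23 to 0.80) and GBP1 (-0.13, -0.35 to 0.10), which was at 0.05 on slide 2 alone, and none passed. PDCD1LG2 (-0.30, -0.65 to 0.06) and PPARG (-0.21, -0.48 to 0.07) had the smallest p among IL-4 response genes and did not pass. Nor did CCR7 (-0.34, -0.78 to 0.11) and CD83 (-0.30, -0.90 to 0.31) among dendritic cell markers, or CD86 (-0.44, -1.21 to 0.32) and HLA-DMB (-0.35, -0.94 to 0.23) among antigen presentation genes. On slide 1 alone camera called none of the 5 lists, and without donor 4 it called 2 lists, with the IL-4 response, dendritic cell and interferon lists at adjusted p = 0.214, 0.124 and 0.349. The interferon list was also lost without donor 1 (median 0.03, adjusted p = 0.114) and the dendritic cell list without donor 5 (adjusted p = 0.0548), although its median was then -0.13.

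KFR was compared with IL-4 to find whether raised affinity for the IL-13 receptor chain changes the response. The 640 genes differed by a median of 0.10, with the largest difference for TIFAB at 0.61, and 35.2% changed more with KFR. No gene passed in limma, where 268 had an unadjusted p under 0.05, nor with donor as a block, where 863 did. The smallest p were those of 3 long noncoding RNAs, the growth factor PSPN (-0.29, -0.45 to -0.13) and RCN3 (0.42, 0.16 to 0.68). PSPN was dim (mean log2 intensity 6.74). The interval lay within 2-fold for 82.2% of the 640 genes, and for 99.8% with donor as a block. Interferon-stimulated genes were higher with KFR by camera (median 0.15, adjusted p = 0.0028), a call lost at adjusted p = 0.795 with an estimated correlation, by fry (adjusted p = 0.886) and without donor 4, where no list was called although the median was still 0.15 (adjusted p = 0.133). Among them GBP4 was at 0.38 (-0.06 to 0.83), USP18 at 0.29 (-0.10 to 0.67) and IFI27 at -0.21 (-0.38 to -0.03), which turned to 0.04 under median centring.

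KFR and Super-4 were compared to find whether a shift toward either receptor type matters. The 640 genes differed by a median of 0.13, and 72.3% changed more with KFR. CXCL1 differed most in this set and was lower with KFR, at -0.79 (-1.46 to -0.13), as was CCL2 at -0.71 (-1.47 to 0.05), and neither passed (adjusted p = 1.00). For CXCL1 a second probe, nearly as bright, differed less, with -1.92 with KFR and -1.64 with Super-4 over GM-CSF alone. The growth factor EREG was at -0.36 (-0.77 to 0.05), and H2BC6, a histone gene, was the 1 gene with a symbol among the 5 smallest p (0.35, 0.16 to 0.54). H2BC6 was dim (mean log2 intensity 6.37). No gene passed in limma, where 323 had an unadjusted p under 0.05, nor with donor as a block, where 1260 did. The interval lay within 2-fold for 83.3% of the 640 genes, and for 99.8% with donor as a block. Inflammatory cytokines and chemokines were lower with KFR by camera (median -0.16, adjusted p = 8.96e-04), a call lost at adjusted p = 0.361 with an estimated correlation and by fry (adjusted p = 0.818).

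**Figure D3:**
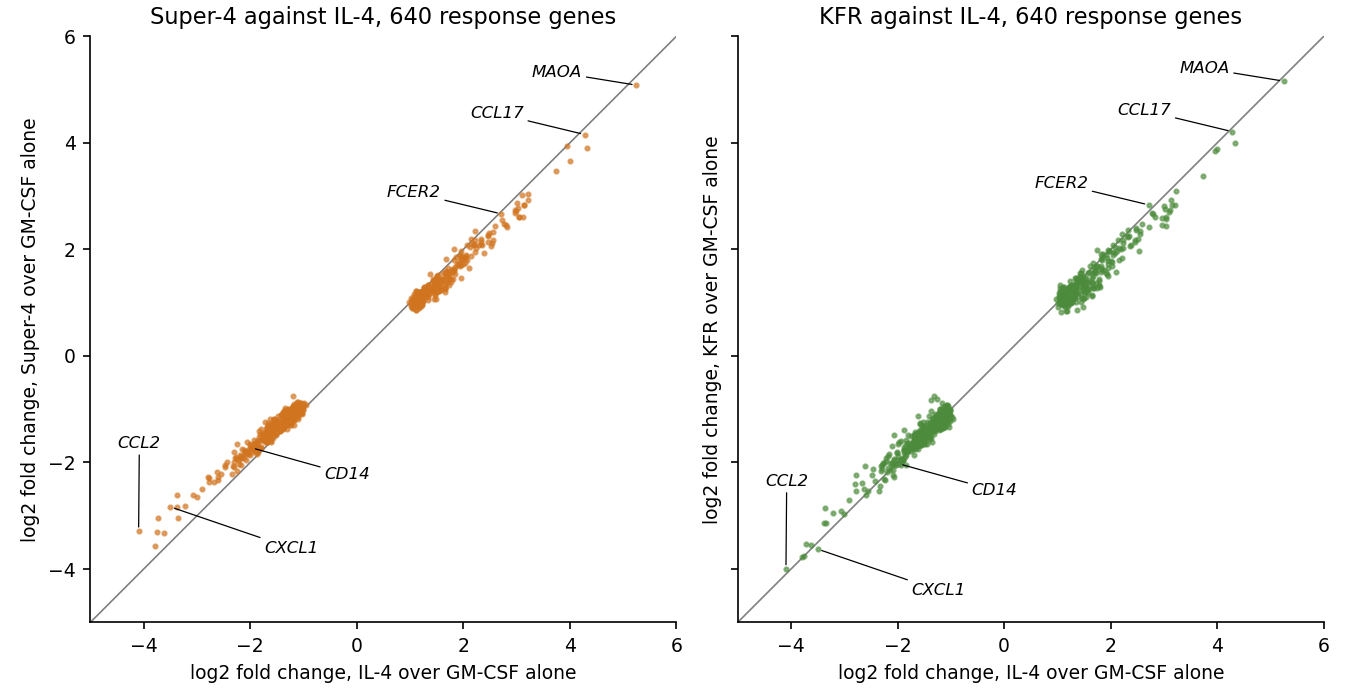
Mean log2 fold change over GM-CSF alone with Super-4 (left) and KFR (right) on the vertical axis, against that with IL-4 on the horizontal axis, for 640 genes that changed at least 2-fold in the mean of the 3 cytokines, with the line of equal response. Points lie along the line, with median absolute differences of 0.16 and 0.10.

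The IL-4 response list gave the size of the response in each donor. Its score was 1.75 ± 0.17 with IL-4, 1.62 ± 0.14 with Super-4 and 1.65 ± 0.21 with KFR (mean log2 ratio ± SD, n = 5). Super-4 differed from IL-4 by -0.129 (exact permutation p = 0.198, exact sign-flip p = 0.125), KFR from IL-4 by -0.0937 (p = 0.492 and 0.313 in the same exact tests) and KFR from Super-4 by 0.035 (p = 0.762 and 0.438 in the same exact tests), all less than the spread between donors. After adjustment for the 3 comparisons the exact permutation p were 0.595, 0.738 and 0.762. Leaving out each donor in turn gave -0.163 to -0.0702, -0.158 to -0.063 and 0.0048 to 0.0688. With arrays scaled to the same spread KFR differed from IL-4 by -0.359 (exact permutation p = 0.0238, unadjusted) and from Super-4 by -0.265, and from Super-4 by -0.0826 with the processed signals and with the deposited ratios. On slide 1 alone, where donor 3 was present with Super-4 but not with KFR, KFR differed from Super-4 by -0.0125, and by 0.0358 over the 2 donors with both. Over the 640 genes, mean response size was 1.61 ± 0.27, 1.44 ± 0.31 and 1.53 ± 0.29. Super-4 was lower than IL-4 in 5 of 5 donors, by -0.172 on average (89.3% of IL-4, exact permutation p = 0.397, exact sign-flip p = 0.0625, the smallest that 5 donors allow), and KFR was higher than Super-4 in 5 of 5 donors, by 0.0897 (exact permutation p = 0.484, exact sign-flip p = 0.0625). KFR differed from IL-4 by -0.0819 (exact permutation p = 0.556, exact sign-flip p = 0.188). Under median centring these differences were -0.167, 0.0861 and -0.0809 over the same 640 genes, in the same order, but 0.0163, -0.014 and 0.00225 over 7967 response genes chosen again. KFR differed from Super-4 by 0.122 with the processed signals and with the deposited ratios over the same genes, but by -0.0537 and -0.0566 over 1907 and 1909 genes chosen again. With scaled arrays this difference changed sign over the same genes (-0.179) and over 632 chosen again (-0.182). On slide 2 alone, where donor 1 was present with IL-4 only and donor 3 with KFR only, Super-4 and KFR differed from IL-4 by -0.0756 and -0.0182 over the same genes. Over 992 genes chosen again they differed by 0.0255 and 0.0577, and there over the 2 donors with both by -0.148 and -0.0878.

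**Figure D4:**
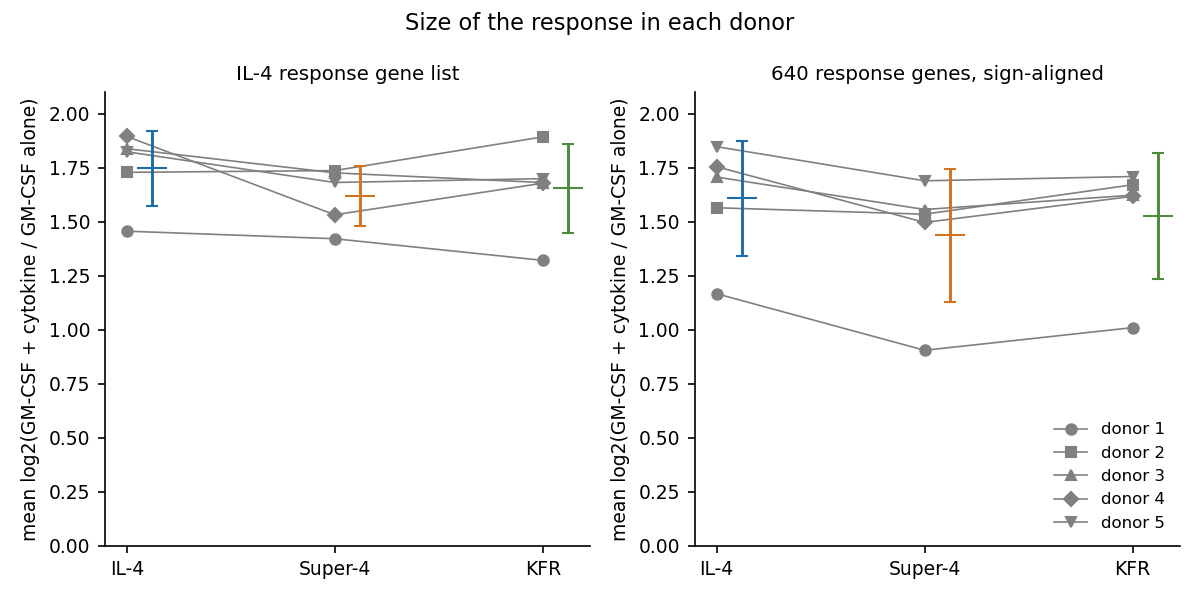
Mean log2 ratio over GM-CSF alone (vertical axis) for the IL-4 response list (left) and for 640 response genes aligned by direction (right), with 1 grey line per donor and the mean ± SD of 5 donors in colour. Response size with Super-4 lies below that with IL-4 in 5 of 5 donors, and under median centring the mean difference was -0.167 over these genes and 0.0163 over 7967 response genes chosen again.

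The 3 cytokines changed largely shared sets of genes. IL-4 and Super-4 had 5282 called genes in common with the same direction (2072 up and 3210 down, 89.2% of the shorter list), IL-4 and KFR 5574, and Super-4 and KFR 5083, and no gene moved in opposite directions. Independent lists of these lengths would share 939, 1147 and 1037. Unchanged genes, simulated 100 times with the measured correlation between ratios of a donor, gave at most 1 shared gene. Each gene was drawn independently there, without correlation between genes or an effect of slide or dye, so this baseline is too low for real arrays. Fold changes correlated at 0.98, 0.97 and 0.96 across genes, which are not independent replicates, against 0.40 in the simulation. That 0.40 is the correlation between ratios of a donor that the simulation was given (0.399). Different donors for the 2 cytokines remove any shared control, but not a dye effect common to all arrays. The median correlations were then 0.89, 0.87 and 0.85 and the median numbers of shared genes 1117.5, 1419 and 1132. These numbers varied widely between the 20 splits (155 to 2330, 214 to 3222 and 158 to 3032), and independent lists would share a median of 121, 163 and 134.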

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

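Tests of the smaller response with Super-4 and of the 3 arrays of donor 1 were chosen only after the results were seen, and the range that decides those of the 3 arrays was widened once their values were known. Also chosen afterwards were the intervals of list medians, while the tests of dye bias, other blood cells and regrouped samples were chosen before. A value is given here where 1 of 5 donors lay far from the nearest of the others, measured against the range of the group. Chance gives this in about 1 in 20 groups, and it occurred in 26 of the 259 groups tested.

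Donor 1 stood apart in 20 of the 21 values of named genes among them. With IL-4, donor 1 was lowest for SLA (3.28), SPINT2 (2.61) and MS4A4A (2.51) and fell least for CXCL6 (-1.77) and PPBP (-1.45). With Super-4 it was lowest for TGM2 (1.46) and CD36 (0.26) and highest for OLIG1 (-2.30), CCL7 (-0.70), MARCO (-0.66) and PPBP (0.0933). With KFR it was lowest for SLA (2.48), CCL26 (3.52), SPINT2 (1.89), CD36 (0.58), CD86 (0.0742), CIITA (0.55), CD14 (-2.98) and FPR1 (-1.72) and highest for CXCL3 (-2.50). The remaining value was that of PIM1 with KFR in donor 5 (-1.54). Without donor 1, CXCL6 with IL-4 was at -3.77, CCL7 with Super-4 at -3.38 and CD86 with KFR at 1.71, and each still passed. Without the first 3 arrays of donor 1, 6996, 5990 and 7559 genes passed with IL-4, Super-4 and KFR.

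Response size over the 640 response genes was also lowest in donor 1 with Super-4 (0.904) and with KFR (1.01). The spike-in controls of donor 1 had the lowest intercept with Super-4 (-0.335) and KFR (-0.374, log10 scale). On the KFR array of donor 3, 82.7% of gene spots lay well above background in Cy5, more than on the other KFR arrays. The KFR array of donor 2 did not meet the rule above. It had the lowest share well above background in Cy3 of all arrays (43.1%) and the most flagged spots (1099). Donor 2 was the only donor with KFR above IL-4, for the list score (1.89 against 1.73) and for response size (1.67 against 1.56).

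The first 3 arrays of donor 1 resembled each other (correlation across genes at least 0.887) more than they did those of other donors (0.426 to 0.623, against 0.564 to 0.889 between any 2 of donors 2 to 5). Whether slide 1 set them apart cannot be told from these values. The 3 arrays correlated at most at 0.623 with those of other donors, against 0.796 to 0.860 between the other 2 donors on that slide. This gap rests on those 2 donors alone. The 0.623 lay above the lowest value between donors 2 to 5 over both slides (0.564), so the test could not decide. Their median with the other donors' arrays of slide 1 was 0.578, within the range of donors 2 to 5 over both slides. An effect of the slide therefore stays open, and an effect on some of its arrays was not tested. Their median Cy3 signal (51.7 to 56.3) was the lowest of all arrays (57.6 or more on the others). Their median Cy5 signal was not low (51.0 to 54.2, against a median of 49.3 over all arrays). Weak signal in Cy3 stays open too. Over the 5425 brightest genes their correlations (median 0.655, highest 0.700) overlapped the 0.677 to 0.949 between any 2 of donors 2 to 5. They lay below the 0.816 to 0.9 on slide 1. Labelling stays open and untested, since the spike-in intercepts of the 3 were also the lowest (-0.283 or less, against -0.0969 or more on the others). A difference between donors and an effect of that donor's GM-CSF sample stay open and untested as well, and the labels do not say whether the 3 arrays share that RNA.

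The smaller response with Super-4 than with IL-4 may reflect the variant itself or its handling. The repeat array is argued against, since without it the difference was -0.126 and lower in 5 of 5 donors. A smaller spread on the Super-4 arrays is argued against, since after scaling every array to the same spread it was -0.147, again lower in 5 of 5 donors. Chance differences between donors cannot be told apart from it, because the exact sign-flip p of 0.0625 is the smallest that 5 donors allow. Over response genes chosen again the difference was 0.0163 under median centring and 0.0255 on slide 2 alone, where donor 1 was present with IL-4 only, but over the same 640 genes it was -0.167 and -0.0756.

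The changes against GM-CSF share 1 dye arrangement, so a bias of single probes might add to them, small ones above all. It is argued against as the whole cause by second probes at other positions, which had the same sign as the called probe for at least 79.4% of genes (95% interval 77.4% to 81.2%, 1792 genes, KFR), and for 94.8% to 97.2% of genes changed at least 2-fold. Their log2 fold change was smaller, at a median of 0.377 to 0.437 of that of the called probe, and 0.539 to 0.577 for genes changed at least 2-fold. The sizes are thus less well borne out than the signs. The cells had been enriched by depletion and CD14 selection, but other blood cells in 1 arm cannot be told apart by these values. The list median farthest from 0 over 6 cell types and 3 cytokines was 0.0729 (neutrophil markers, KFR), inside the limit of 0.5 set beforehand. The 95% interval of the median, added later, lay within 0.5 of 0 in 6 of 18 cases, all 6 of them T and B cell markers (-0.204 to 0.208). In lists of 7 or 8 members this interval runs from the lowest to the highest member, so 1 gene can decide it. For neutrophil markers its upper end was the value of CXCR2 (1.80, 1.45 and 1.30 with IL-4, Super-4 and KFR). Platelet markers fell for 3 of 11 with none up, and medians outside that test reached 0.355 for plasmacytoid dendritic cell markers (KFR) and -0.169 for basophil and mast cell markers (IL-4). The effect of the cytokines stays the open explanation that the design names.

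Turning the sign of each donor's ratios gave 16 patterns per comparison with GM-CSF, too few for a share under 0.05. The real counts were 6587, 5924 and 7256 with IL-4, Super-4 and KFR, against highest other counts of 0, 703 and 3090, so 1 pattern, the real one, was as large. Between cytokines the real count was 0 each time, so all 100 of the splits drawn were as large whatever the data, and their number decides nothing about chance. The highest other counts were 823, 3059 and 3942 for Super-4 and IL-4, KFR and IL-4, and KFR and Super-4, each in the only split above 0, which points to a structure of the samples. For the last 2 pairs that split set slide 1 against slide 2, and so donors 1 and 2 against donors 4 and 5. Within either slide the counts between cytokines were 0. The 12 drawn splits that parted the ratios of all 5 donors, the real one among them, gave at most 0, whereas the other 88 kept some donors' ratios together.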

How the results depend on the processing

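The alternatives that use single slides, leave out arrays that stood apart or put the repeat array in place of the mean were chosen only after the data were seen, as were response size, its value over the same 640 genes and the comparison over donors with both cytokines. Of 6083 values of named genes against GM-CSF under these and the other alternatives, 5842 kept direction and side of the threshold, 173 lost the call, 29 gained it and 39 changed direction. Between cytokines 823 of 825 values of named genes were unchanged. For lists 560 of 666 values were unchanged, 98 lost the call and 8 changed direction. For counts 319 of 387 stayed within 1.5 times, and for scores and response size 193 of 213 were unchanged. No alternative called a gene between cytokines. Unless a sentence says otherwise, the cause was not tested. Signal over background is 1 limit of precision, with 40.4% of gene spots well above background in Cy5 on the dimmest array.

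Median centring in place of loess called 16263, 16536 and 15865 genes with IL-4, Super-4 and KFR, 7972, 8325 and 7575 of them at least 2-fold, with overlaps of 15589 (IL-4 and Super-4), 14939 (IL-4 and KFR) and 15098 (Super-4 and KFR). It centres each array on all its spots, and the median of the genes tested then lay at -0.61, -0.64 and -0.54. It called 14 lists with KFR and 3 between KFR and IL-4. Response size differed by 0.0163 (Super-4 minus IL-4), 0.00225 (KFR minus IL-4) and -0.014 (KFR minus Super-4) over 7967 response genes chosen again, and by -0.167, -0.0809 and 0.0861 over the same 640 genes. Antigen presentation genes read -0.90, -1.02 and -0.88, immediate early genes -1.13, -1.12 and -1.10, housekeeping genes -1.26 with Super-4 and myeloid transcription factors -1.20 with IL-4. With IL-4, Super-4 and KFR in turn, the log2 ratios read -0.94, -1.004 and -0.93 for MRC1, -0.46, -0.64 and -0.48 for CISH, -0.87, -0.97 and -0.76 for SOCS1, -0.63, -0.65 and -0.73 for HSPA1A, and -0.16, -0.27 and -0.18 for HSPB1. They read -0.37, -0.45 and -0.27 for FOS, -0.093, -0.217 and -0.0638 for STAB1, -1.13, -1.18 and -1.27 for CSF1R, -0.83, -1.02 and -0.99 for FCN1, and -0.50, -0.72 and -0.55 for PIM3. HLA-DPA1 read -0.91 with IL-4 and -0.89 with KFR, and with Super-4 CD274 read -0.89, ACTB -0.92, PPIA -1.06 and CCL5 -0.14. IFI27 between KFR and IL-4 read 0.0405.

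With the processed signals of Feature Extraction 2350, 2068 and 1830 genes changed at least 2-fold, and the deposited ratios gave 2364, 2105 and 1839. KFR minus Super-4 was then -0.0826 for the list score with both, and -0.0537 and -0.0566 for response size over 1907 and 1909 genes chosen again, but 0.122 with both over the same 640. Scaling arrays to the same spread gave list scores of -0.359 for KFR minus IL-4 (exact permutation p = 0.0238, past the threshold only without adjustment for the 3 comparisons) and -0.265 for KFR minus Super-4, and a response size of -0.182 for KFR minus Super-4 (-0.179 over the same 640 genes). The mean of all probes gave IL2RG 0.073, 0.0547 and 0.174 with IL-4, Super-4 and KFR, since its second probe has the opposite sign. An adjusted p under 0.01 left overlaps of 3208 (IL-4 and Super-4), 3576 (IL-4 and KFR) and 3086 (Super-4 and KFR), being stricter. Different donors on the 2 sides left 1117.5, 1419 and 1132, with fewer donors in each list. With an estimated correlation camera called 4, 3 and 3 lists with IL-4, Super-4 and KFR and 0 for each pair of cytokines, and fry called 19, 20 and 18 and 0 for each pair.

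Donor as a fixed block called 9050 genes with Super-4, overlaps of 8056 (IL-4 and Super-4) and 7829 (Super-4 and KFR), and 10, 2 and 3 lists for Super-4 against IL-4, KFR against IL-4 and KFR against Super-4. Leaving out each donor in turn gave 3941 to 5877 genes with Super-4, an overlap of 3336 to 5090 for Super-4 and KFR, and 2 to 7, 0 to 2 and 1 to 2 lists for the same 3 pairs. Slide 1 alone, with 2 or 3 donors, called 3288, 3023 and 1879 genes with IL-4, Super-4 and KFR, 478 (IL-4) and 406 (KFR) at least 2-fold, and 0, 2 and 4 lists for the 3 pairs, and its list score for KFR minus Super-4 was -0.0125. Donor 3 was present there with Super-4 but not with KFR, and over the 2 donors with both that score was 0.0358. Over these 2 donors KFR minus IL-4 was 0.0569 for the list score and 0.108 for response size. Slide 2 alone called 1078 (Super-4) and 1108 (KFR) genes at least 2-fold and 0 lists for KFR against IL-4 and 3 for KFR against Super-4. There, response size differed by 0.0255 (Super-4 minus IL-4) and 0.0577 (KFR minus IL-4) with donor 1 in the IL-4 group only and donor 3 in the KFR group only. Over the 2 donors with both it differed by -0.148 and -0.0878. Over the same 640 genes it differed by -0.0756 and -0.0182, and GBP1 between Super-4 and IL-4 was at 0.0509. Without the first arrays of donor 1 the 3 pairs had 3, 0 and 0 lists, and response size for KFR minus IL-4 was 0.0148, with donor 1 in the IL-4 group only, 0.000209 over the same 640 genes and -0.0464 over the 4 donors with both. Without these and the KFR array of donor 3, Super-4 against IL-4 and KFR against Super-4 had 3 lists each, and response size for KFR minus IL-4 was 0.0256, 0.0112 over the same 640 genes and -0.0489 over the 3 donors with both. Without that KFR array alone, KFR against IL-4 and KFR against Super-4 had 2 lists each. Without the repeat array they had 0 and 2.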

Other observations

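The tests in this part were planned apart from the choice of 4 genes, CXCR2, CD36, SCARB1 and PPBP, which were chosen only after their values were seen. Several gene groups moved in both directions at once. Among 23 C-type lectins and scavenger receptors 8 rose, 7 fell and 8 did not pass with IL-4, the same adjusted over the list alone, with a camera adjusted p of 0.918, a median of -0.04 and a mean of 0.10. CLEC5A, an activating lectin of myeloid cells, fell to -3.00 ± 0.15 with IL-4, -2.65 ± 0.25 with Super-4 and -2.96 ± 0.23 with KFR (log2 ratio, mean ± SD, n = 5). CLEC4D, which recognises mycobacterial lipids, fell to -1.80 ± 0.20, -1.73 ± 0.19 and -1.79 ± 0.30, and MARCO fell as well. CD209 and CLEC10A rose, as did the lipoprotein receptors SCARB1 (2.22 ± 0.55, 2.34 ± 0.57 and 2.13 ± 0.56) and CD36 (2.07 ± 0.50, 1.81 ± 0.87 and 1.93 ± 0.76).

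Of 18 chemokine receptors 3 rose, 8 fell and 7 did not pass with IL-4, the same adjusted over the list alone, with a median of -0.18 and a camera adjusted p of 0.102. The receptors for complement C3a (C3AR1, -1.91 ± 0.23) and for formyl peptides (FPR2, -1.28 ± 0.24, and FPR1) fell, as did CCRL2 (-0.69 ± 0.09). CXCR2, the receptor for the chemokines CXCL1 and CXCL3, rose by 1.80 ± 0.73, 1.45 ± 0.49 and 1.30 ± 0.24 with IL-4, Super-4 and KFR, while its ligand PPBP fell to -2.43 ± 0.57, -2.00 ± 1.18 and -2.35 ± 0.62. Of 20 JAK-STAT feedback and immediate targets 3 rose, 8 fell and 9 did not pass (3 and 9 adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 0.195. BCL6 and the kinase PIM1 fell to -1.30 ± 0.24 and -1.19 ± 0.17 with IL-4. PIM3 rose by 0.96 ± 0.15 and CISH by 1.00 ± 0.07, and both read as lower under median centring (-0.50 and -0.46).

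By the correlation of their GM-CSF channels, 2 of 16 arrays lay closest to an array of a donor other than the one their label gives. After the mean of each cytokine was removed, ratios of the same donor correlated across genes at a median of 0.653 (0.0318 to 0.818, 15 pairs).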
